A study of Mus musculus with 6 samples.

How the data were processed

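RNA-seq was carried out on cochleae of 6 mice, 3 homozygous for an engineered allele of Hgf and 3 wild-type littermates, per the labels. The allele carries a 10 bp deletion in intron 5 of Hgf together with a Neo selection cassette, per the genotype labels. Total RNA was depleted of ribosomal RNA and reverse transcribed with random primers, and the libraries were read as pairs of 93 bases, per the labels' protocols. The mice were between 5 and 27 weeks old, per the labels' protocols. The age, sex and litter of each mouse were not given in the sources used here.

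The authors mapped the reads to GRCm38 (GENCODE release M11) with STAR 2.5.2 and tested them with DESeq2, per the labels and the submitters' processing notes. The program that counted reads per gene and its strand setting were not given in the sources used here, so reads of overlapping or antisense genes may not be separable. The authors deposited unnormalized whole-number read counts per gene for each library. They also deposited a table of their own DESeq2 comparison, with a mean signal per feature (counts divided by size factors), log2 fold changes with standard errors, a test score per feature (the fold change divided by its standard error), and p-values. A deposited table of transformed log values was not used here, because the counts it was made from were tested directly.

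The count table held 48733 rows, of which 48709 were mouse genes. The other 24 rows were spike-in and transgene sequences; they took between 0.0015% and 0.0045% of the counts of a library and stayed out of library sizes and tests. Symbols and coordinates were taken by gene identifier from GENCODE release M21, which is on the same build, and 48349 identifiers matched. Mouse gene counts summed to between 24005234 and 42312291 per library. CPM are counts scaled to a common library total. For a group without any count, the floor was 3 counts over its 3 libraries. Intervals and floors cover counting error only. All 15 pairs of libraries were compared by a chi-square test over genes with a mean count of 10 or more. The statistic per degree of freedom was between 20.5 and 50.8, so no library was a repeat of another.

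Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, normalization was by TMM, and the quasi-likelihood F test (glmQLFit and glmQLFTest) was two-sided with group as the only term. Adjusted p-values are Benjamini-Hochberg values over the 20733 genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as the fold change divided by the square root of F. CPM values of mouse genes use TMM-scaled library sizes, and group values are mean ± SD. CPM of transgene sequences, and counting bounds on single libraries, use the unscaled mouse gene counts of a library. A first run used the bias-adjusted version of the quasi-likelihood fit; after its results had been seen, the default of this edgeR version was made the main fit, because the planned test named the function without options. Both versions called the same 7 genes, and both are reported in the closing section.

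A total of 31 gene lists, of cochlear cell types, tissues that can accompany a dissected cochlea, and pathways, were fixed before the data were examined. The pigment cell and strial intermediate cell lists were included in the knowledge that the published account of this strain concerns these cells. Lists were tested with camera on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01 (limma 3.58.1). Estimated correlations and fry were alternatives. Named genes followed a rule fixed before the data were examined. It took Hgf, then up to 12 genes per direction with the largest absolute log2 fold change among those past the threshold, with no overlap between groups and a mean of at least 1 CPM in a group. Where fewer than 10 genes passed, the genes with the smallest unadjusted p filled the places up to 10. Up to 4 members per list with the smallest p were added. Gene models without a name and pseudogenes were counted only. Genes named outside this rule are identified as such.

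On simulated counts with known changes, made from the means, spreads and library sizes of these 6 libraries (20486 genes tested), the edgeR test recovered 39 of 50 genes raised 2-fold and 50 of 50 raised 4-fold. It recovered 29 of 50 genes lowered to a fold of 0.5 and 48 of 50 lowered to 0.25. It called 20 of 20533 genes simulated without a change, a total taken before the filter. Changed genes were drawn only from those above a minimum mean count. The alternatives were RLE and upper-quartile normalization, no filter and a stricter filter (at least 1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, covariates for Xist and for the erythroid list, a threshold of 0.1, and leaving out each library in turn. Tests of single values used scipy 1.17.1. Replicate numbers were given in accession order and pair no samples.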

Results

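Gene expression was measured by RNA-seq of total RNA from the cochlea, the hearing organ of the inner ear, in 3 wild-type mice and 3 mice homozygous for an engineered Hgf allele (knock-in). The strain is a mouse model of DFNB39, a recessive human deafness linked to HGF. Wild-type libraries held 24144106, 29041493 and 42312291 gene counts, and knock-in libraries 34437746, 28451570 and 24005234. Xist, the RNA of the inactive X chromosome, was abundant in 1 library of each group, wild-type replicate 2 and knock-in replicate 3 (25380 and 17489 counts). The Y-linked gene Ddx3y was abundant in the other 2 of each group. The first principal component held 34.7% of the variance of log2 CPM and the second 21.9%, and neither separated the groups.

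The first question was whether the allele altered Hgf RNA. Hgf (ENSMUSG00000028864) encodes hepatocyte growth factor, the ligand of the receptor Met, and lies on chromosome 5 from 16553495 to 16620152 on the forward strand of GRCm38. Intron 5 spans 16572635 to 16576908 in the annotated transcripts Hgf-201 and Hgf-203, and 16566862 to 16572491 in Hgf-204. The exact position of the deletion was not given in the sources used here. Hgf was at 15.6 ± 0.572 CPM (SD, n = 3) in wild-type and 10.07 ± 0.724 CPM (SD, n = 3) in knock-in cochlea, and every knock-in library lay below every wild-type library. The log2 fold change was -0.63 (SE 0.111), 1.55-fold lower in knock-in, and did not pass the threshold in edgeR's quasi-likelihood test (adjusted p = 0.246). In the authors' deposited table its adjusted p was 0.0149, with a log2 fold change of -0.64. Counts per gene do not separate Hgf transcripts.

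The main comparison asked which genes differed between knock-in and wild-type cochlea. Genes of pigment cells were lower in knock-in. Dct, which encodes dopachrome tautomerase of the melanin pathway, fell from 106.5 ± 8.86 to 22.42 ± 2.74 CPM (SD, n = 3 per group), a log2 fold change of -2.25 (SE 0.121). Slc45a2, a melanosomal transporter, fell 6.47-fold, Tyr, which encodes tyrosinase, fell 4.98-fold, and Mlana, a melanosome protein gene, fell 4.24-fold. Hpse, which encodes heparanase, fell 2.0-fold, from 41.75 ± 2.15 to 20.92 ± 2.06 CPM (SD, n = 3 per group). The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called these 5 genes lower and 2 genes higher among 20733, with adjusted p of 0.000179 for Dct, 0.00153 for Slc45a2 and 0.0205 for Tyr, Mlana and Hpse. The calls of Tyr, Mlana and Hpse were lost without wild-type replicate 2, wild-type replicate 3 or knock-in replicate 3, and those of Mlana and Hpse also without wild-type replicate 1, with edgeR adjusted p of 0.079 to 0.141 in these fits. With the erythroid list as a covariate the edgeR adjusted p was 0.0633 for Tyr and Hpse and 0.0729 for Mlana. Their log2 fold changes were about as large, -2.39 (SE 0.28) against -2.32 (SE 0.26) for Tyr, -1.03 (SE 0.12) against -1.0 (SE 0.11) for Hpse and -2.06 (SE 0.26) against -2.08 (SE 0.23) for Mlana. That fit left 3 residual degrees of freedom in place of 4, and the standard errors were larger. At an unadjusted p under 0.05, 407 genes were lower and 526 higher, 4.5% of those tested, no more than that cutoff gives without any change. The groups did not overlap for 1807 genes, Hgf among them. These were 8.7% of those tested, where 10% is the share by chance for 3 against 3. DESeq2 on the same counts called 17 genes lower and 12 higher, and the authors' deposited table lists 19 lower and 15 higher. The authors' higher features include DsRed, a transgene sequence that stayed out of the tests here.

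**Figure D1:**
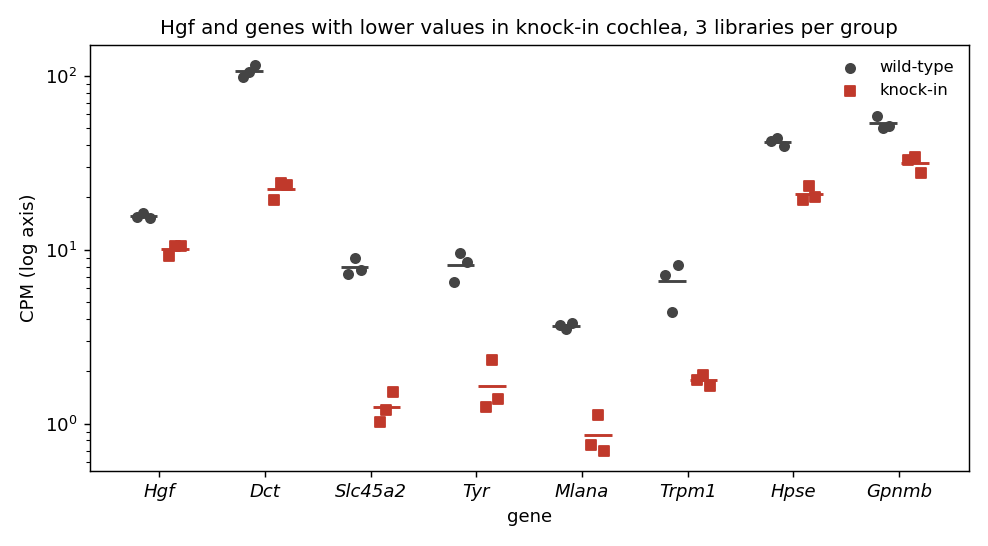
CPM on a log axis of Hgf and 7 genes with lower values in knock-in cochlea; each point is 1 library, 3 per group, and each line is a group mean. The knock-in points lie below the wild-type points for each gene; Dct means are 106.5 CPM in wild-type and 22.42 CPM in knock-in.

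The next 5 places among the lower genes went to genes that did not pass the threshold. Trpm1, a cation channel gene of melanocytes, had a log2 fold change of -1.89 (edgeR adjusted p = 0.0573), and Gpnmb, a melanosome glycoprotein gene, had -0.76 (edgeR adjusted p = 0.137). Gsta2, a glutathione transferase gene, had -2.28, and the immunoglobulin variable segments Ighv1-15 and Igkv14-111 had -1.78 and -2.16. Trpm1 passed without wild-type replicate 2 (edgeR adjusted p = 0.0112) and Igkv14-111 without wild-type replicate 3 (edgeR adjusted p = 0.0177). With the Xist covariate Trpm1 and Gpnmb passed (edgeR adjusted p = 0.01107 and 0.02791). DESeq2 called Trpm1, Gpnmb, Ighv1-15 and Igkv14-111, and edgeR with no filter on low counts called all 5. Gsta2 and the variable segments belong to families of near-identical genes that can share reads, so their values are uncertain.

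The pigment cell list had lower values in knock-in. Of its 16 tested members, 15 had negative log2 fold changes, 4 fell over all genes tested and 7 fell when adjusted over the list alone (camera adjusted p = 1.7e-14; adjusted p = 0.0332 with an estimated correlation). The call with an estimated correlation was lost without any single library (adjusted p = 0.0808 to 0.22) and with the Xist or erythroid covariate (adjusted p = 0.138 and 0.121). The median was -0.3 because other members hardly differed. Pmel, Kit and Tyrp1 were chosen after their values were seen. Pmel, a structural protein gene of melanosomes, was at 7.51 ± 1.14 and 7.05 ± 1.14 CPM, and Kit, the receptor gene for stem cell factor, at 43.75 ± 1.32 and 42.57 ± 2.83 CPM in wild-type and knock-in (SD, n = 3 per group). The direction of Pmel turned to 0.03 without wild-type replicate 3. Tyrp1, a melanin pathway gene, had a log2 fold change of -1.13 and passed when adjusted over the list alone.

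Intermediate cells are the melanocyte-derived cells of the stria vascularis, the epithelium that secretes endolymph. All 9 tested members of their list had negative log2 fold changes, with a median of -0.43 (camera adjusted p = 5.14e-09; adjusted p = 0.0457 with an estimated correlation). Dct is also in the pigment cell list. Without it the median was -0.41 and camera with the preset correlation still called the list (adjusted p = 5.46e-06). The call with an estimated correlation was lost without Dct (adjusted p = 0.106). With all 9 genes that call was also lost without any single library (adjusted p = 0.119 to 0.232), with the stricter filter (adjusted p = 0.0505) and with the Xist or erythroid covariate (adjusted p = 0.138 and 0.121). In the main fit the estimated correlation was 0 for the pigment cell list and -0.03 for this list. For both lists the adjusted p was higher than with the preset correlation. Correlation between genes therefore did not raise it. Besides Dct, 3 members passed when adjusted over the list alone. These were Gsta4, a glutathione transferase gene (-0.78), Met (-0.43) and Kcnj10, the potassium channel gene of intermediate cells (-0.43). None of the 3 passed over all genes tested.

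Lists of the other strial cells, fibrocytes, hair cells and supporting cells were not called in the main fit. The supporting cell list (camera adjusted p = 0.0534) was called with the stricter filter (0.0291), without wild-type replicate 2 (0.00119) and without knock-in replicate 3 (0.0451). The HGF-MET list was called without wild-type replicate 3 (0.0474). With an estimated correlation each of these calls was lost (adjusted p = 0.915, 0.521 and 0.804 for the supporting cell list and 0.859 for the HGF-MET list). Strial marginal cell genes had a median log2 fold change of -0.01 over 13 genes, with Wnk2 at 0.27 and Bsnd at 0.29. Basal and spindle cell genes had 0.03 over 8, with Sparcl1 at -0.17 and Sox8 at 0.15. Spiral ligament fibrocyte genes had 0.04 over 12, where Otos (-0.51) passed when adjusted over the list alone and Car3 was at 0.61. Hair cell genes had -0.01 over 20, with Strc at 0.45 and Pou4f3 at -0.31. Supporting cell and tectorial membrane genes had 0.15 over 14, with Ceacam16 at 0.27 and Otoa at 0.25. The hereditary deafness list had -0.01 over 69 genes, the HGF-MET signalling list -0.06 over 21, with Plaur at -0.41, and the list of genes neighbouring Hgf 0.02 over 13. Of these genes, only Otos passed any of the tests in the main fit.

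**Figure D2:**
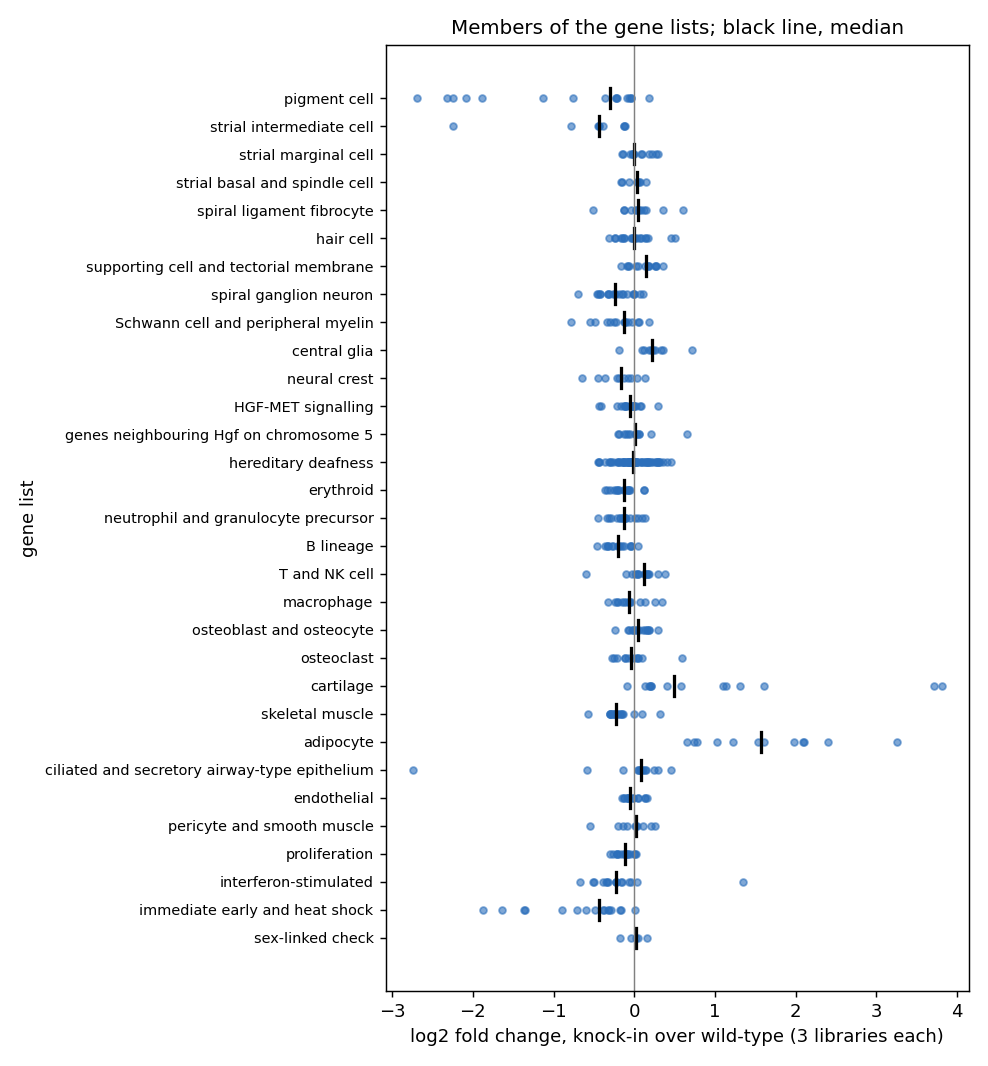
Log2 fold change, knock-in over wild-type (3 libraries each), of each tested member of the 31 gene lists; each point is a gene and each black line a list median. Adipocyte members lie to the right, with a median of 1.57, and the strial intermediate cell members lie to the left, with a median of -0.43.

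The genes with the smallest p among those higher in knock-in included several known from glands and cartilage. Car6, a secreted carbonic anhydrase gene of salivary glands, rose (edgeR adjusted p = 0.0205), with 3 counts over the wild-type and 359 over the knock-in libraries, a ratio of 135 (95% counting interval 45.8 to 658). Its call was lost without wild-type replicate 1, 2 or 3 (edgeR adjusted p = 0.0945, 0.0972 and 0.141) and with the erythroid covariate (edgeR adjusted p = 0.0729), where its log2 fold change was 7.56 (SE 0.92) against 6.97 (SE 0.74). Its log2 fold change of 6.97 was 7.94 without wild-type replicate 1, 6.22 without wild-type replicate 3 and 6.35 without knock-in replicate 3. The second gene called higher, ENSMUSG00000109486, has no name and was chosen after its values were seen. It rose 1.79-fold, from 15.58 ± 0.971 to 27.85 ± 1.55 CPM (SD, n = 3 per group; edgeR adjusted p = 0.0478), and the call was lost when any single library was left out and with the erythroid covariate, where the log2 fold change was 0.88 (SE 0.12) against 0.84 (SE 0.1). Pip, a gene of glandular secretions, had no count in wild-type and 149 counts in knock-in, at least 45-fold higher by the lower bound of the exact 95% counting interval, and 56-fold against a floor of 3 counts over the group (edgeR adjusted p = 0.0647). Bpifa2, a salivary protein gene, was at 0.491 ± 0.0792 CPM in wild-type and at 7.52, 46.3 and 122 CPM in the knock-in libraries (edgeR adjusted p = 0.102). Folds were 14.8 for C1qtnf3, 13.1 for Col10a1, the collagen gene of hypertrophic cartilage, 14.1 for Matn3, a cartilage matrix gene, 9.12 for Chia1, 3.32 for Cyp2e1, 3.06 for Wfdc12 and 4.76 for Lncbate1, none past the threshold. Without knock-in replicate 1, Pip, Bpifa2, C1qtnf3, Col10a1, Matn3 and Chia1 passed (edgeR adjusted p = 0.000275 to 0.0256). With the Xist covariate Pip and Bpifa2 passed (edgeR adjusted p = 0.0108 and 0.01998), and in limma-voom Pip did (adjusted p = 0.002837). DESeq2 called Pip, Bpifa2, C1qtnf3, Col10a1 and Matn3, and edgeR with no filter called these, Chia1 and Cyp2e1. Single libraries moved some values: log2 fold changes went from 3.71 to 3.03 for Col10a1 and from 3.81 to 3.14 for Matn3 without knock-in replicate 2, and from 6.91 to 5.79 for Bpifa2 and 3.19 to 2.16 for Chia1 without knock-in replicate 3.

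**Figure D3:**
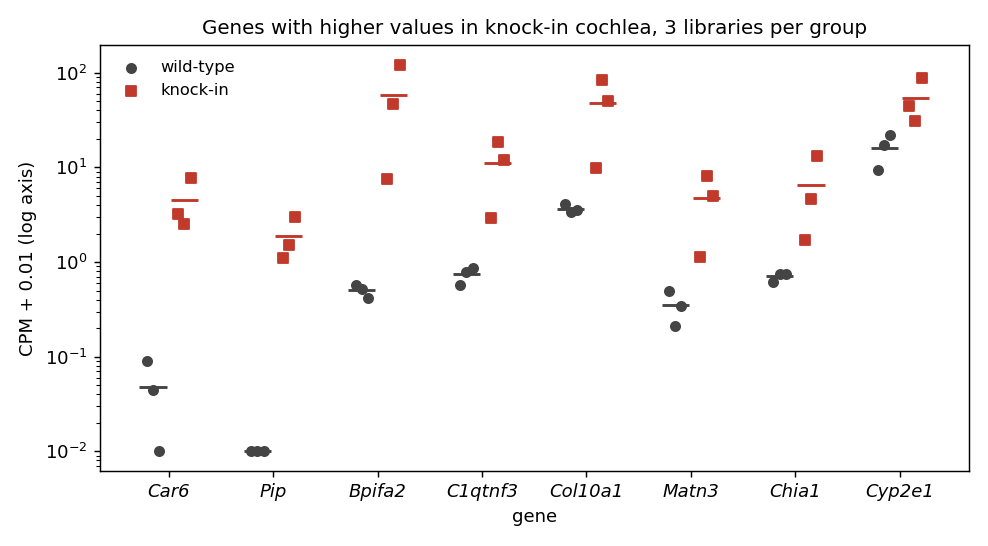
CPM + 0.01 on a log axis of 8 genes with higher values in knock-in cochlea; each point is 1 library, 3 per group, and each line is a group mean. Bpifa2 spans 7.52 to 122 CPM among knock-in libraries, against a wild-type mean of 0.491 CPM.

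All 12 adipocyte list members had positive log2 fold changes, and all 12 passed when adjusted over the list alone, but none over all genes tested. Cidec was at 2.08, Cidea at 2.4, Plin1 at 1.61 and Pparg at 0.74. Without knock-in replicate 3, Cidec was at 1.21 and Plin1 at 0.97. Of 14 cartilage members, 13 were positive and 7 passed when adjusted over the list alone, with Acan at 1.14 and Snorc at 1.6. Without knock-in replicate 1, Acan passed over all genes (edgeR adjusted p = 0.0189). With no filter, Acan, Cidec, Cidea and Plin1 passed. Camera called both lists (adjusted p = 2.1e-09 and 1.73e-07), and both calls were lost with an estimated correlation (adjusted p = 0.693 for each). Against the wild-type mean, the adipocyte score was 1.49, 0.59 and 2.51 log2 units in the knock-in libraries and -0.81, 0.43 and 0.39 in the wild-type libraries.

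Camera also called 8 lists lower, each lost with an estimated correlation (adjusted p = 0.693 for the neural crest list and 0.933 for the other 7). Medians were -0.43 for immediate early and heat shock genes, -0.24 for spiral ganglion neuron, -0.23 for skeletal muscle and for interferon-stimulated genes, -0.16 for neural crest, and -0.13 for Schwann cell, erythroid and neutrophil genes. Egr1 was at 102, 17.6 and 34.9 CPM in the wild-type libraries and 20.6, 17.4 and 11.1 CPM in the knock-in libraries, and Nr4a1 had a log2 fold change of -1.35. Without wild-type replicate 1, Egr1 was at -0.68 and Nr4a1 at -0.45. Nefh and Tubb3 were each at -0.42, Egr2 at -0.78, Prx at -0.54, Ednrb at -0.37, Mitf at -0.21 and Myh4 at -0.58, none past the threshold; Ifi27l2a of the interferon list went the other way, at 1.35, and at 0.46 without knock-in replicate 3. Lists of central glia, B lineage, T and NK cells, macrophages, osteoblasts, osteoclasts, airway-type epithelium, endothelium, pericytes, proliferation and sex-linked genes were not called, with medians between -0.2 and 0.22. Over 10 other settings with the preset correlation, 11 of the 19 lists not called were called in at least 1; with an estimated correlation 0 of the 19 were called in any. The 8 lists called lower in this paragraph were each lost in at least 1, and the other 4 called lists were called in all 10.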

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

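All tests of explanations in this part were chosen after the result was seen. Reads of transgene sequences, which stayed out of the comparisons, exceeded the counting intervals of every wild-type library in some knock-in libraries. The Neo cassette was at 2.062 CPM in knock-in replicate 1 and 6.994 CPM in replicate 2. DsRed was at 1.917 CPM in replicate 1 and 4.604 CPM in replicate 2, and EGFP at 4.675 CPM in replicate 2. Like Neo, both were near the wild-type level in replicate 3, at 0.375 CPM for DsRed and 0.333 CPM for EGFP. Wild-type values were 0.249, 0.344 and 0.284 CPM for DsRed and 0.704, 0.207 and 0.213 CPM for EGFP. The bacterial sequences beta-lactamase and LacZ were at 25.201 and 3.48 CPM in replicate 2, and at 35.701 and 3.749 CPM in replicate 3. Both were present in every library. The wild-type libraries held 12.343, 14.875 and 13.022 CPM of beta-lactamase and 1.657, 1.55 and 1.371 CPM of LacZ. Knock-in replicate 1 was below all of these, at 9.612 and 1.249 CPM.

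Neo counts were 71, 199 and 5 in the knock-in libraries and 5, 8 and 10 in the wild-type libraries, so the library labelled knock-in replicate 3 was at the wild-type level although its label names the Neo allele. A wild-type mouse under that label was argued against by Dct, Tyr and Hgf, whose upper 95% counting bounds in that library were at most 0.828 of the lowest wild-type lower bound. These bounds, on unscaled library totals, cover counting error only; against the spread between mice, Dct was at 23.622 TMM-scaled CPM there and 106.5 ± 8.86 CPM (SD, n = 3) in wild-type. Lower depth was argued against as well, since this library held 0.697 times the gene counts of knock-in replicate 1 but 0.0704 times its Neo counts (95% counting interval 0.0222 to 0.172, which covers counting error only). Whether the cassette differed in this mouse stays open and was not tested.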

How the results depend on the processing

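The fits without mitochondrial genes, with the bias-adjusted quasi-likelihood and with it and no filter together, the list without Dct, and the estimated correlation combined with other choices, were chosen after seeing the data. Dct and Slc45a2 were called in all 17 refits. Of 54 named genes, 52 kept their direction in every planned refit that tested them. The fits without mitochondrial genes and with the bias-adjusted quasi-likelihood were not checked for this. The log2 fold change of Pmel was 0.01 with the erythroid covariate and -0.23 to 0.03 without single libraries, turning without wild-type replicate 3. That of Kit was -0.09 to 0.0 without single libraries, turning without knock-in replicate 2. Genes called higher and lower were 46 and 30 with no filter on low counts, 12 and 17 with DESeq2, and 0 and 3 with the erythroid covariate. The unfiltered bias-adjusted fit called 7 and 7, 14 genes against 76 in the unfiltered default fit, and the Xist covariate called 4 and 7. Genes that passed in the unfiltered default fit but not in the unfiltered bias-adjusted fit included Gpnmb, Gsta1, Gsta2, Gsta4, Ighv1-15, Matn3, Chia1 and Cyp2e1. Acan, Cidec, Cidea, Plin1, Egr1, Amy1, Cst10, Dcpp1 and Mucl2 were among them as well. Leaving out single libraries gave 0 to 13 genes higher and 2 to 8 lower. The most, 13 and 8, came without knock-in replicate 1; no gene was called higher (0) without wild-type replicate 1 or 2, and 1 without wild-type replicate 3 or knock-in replicate 3. Lower genes numbered 3 without wild-type replicate 2 and 2 without knock-in replicate 3. The Hgf log2 fold change of -0.64 passed with no filter (edgeR adjusted p = 0.038) and with DESeq2 (adjusted p = 0.0115). It did not pass in the unfiltered bias-adjusted fit (edgeR adjusted p = 0.266). Over all alternatives it was -0.67 to -0.57, with adjusted p of 0.0115 to 0.797. Lists called were 12, against 2 with an estimated correlation and 2 with fry, and 10 to 13 without single libraries. The pigment cell list was called with the preset correlation in all 10 refits in which lists were tested, and with fry in the main fit. With an estimated correlation it was called in the main fit (adjusted p = 0.0332), with RLE (0.0378) and with the stricter filter (0.0363), and lost with the Xist (0.138) and erythroid (0.121) covariates. It was also lost without wild-type replicate 1, 2 or 3 (0.144, 0.154 and 0.135) and without knock-in replicate 1, 2 or 3 (0.22, 0.0808 and 0.192); without single libraries the range over both correlations was 7.52e-17 to 0.22. Each fit in which the call with an estimated correlation was lost left fewer residual degrees of freedom than the main fit. Against the wild-type mean, the pigment cell score was -0.97, -0.76 and -0.86 log2 units in the knock-in libraries. In the wild-type libraries it was -0.04, -0.02 and 0.06. The cause of the changes between settings was not tested. No paired analysis was possible because the labels number no replicates across groups. The 3 libraries per group recovered 29 of 50 simulated genes lowered to a fold of 0.5. The simulation changed more genes than were called here, which loosens the adjusted threshold, and changed none with low counts. Recovery in these data may thus be lower, and changes of 2-fold or less can be missed.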

Other observations

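The tests of lateral wall tissue and of a uniform cell loss, and the readings of the salivary and NRF2 tests as open although the bounds set in advance were met, were chosen after the results were seen. The sets of immunoglobulin variable segments and of chromosome 9 glutathione transferase genes were also chosen after their values were seen. Of 71 heavy chain segments 49 had negative log2 fold changes (median -0.5), and of 68 kappa segments 49 did (median -0.6). None passed in the main edgeR fit. DESeq2 called 5 segments lower, edgeR with no filter 13, edgeR without wild-type replicate 1 or 3 called 1 and 3, the erythroid covariate and the unfiltered bias-adjusted fit 1 each, and the authors' deposited table lists 6. Such segments can share reads. The B lineage list was not called (camera adjusted p = 0.201) but was with the Xist covariate (0.00483), without wild-type replicate 2 (3.76e-06) and without knock-in replicate 2 (0.00282), each lost with an estimated correlation. Its score, in log2 units against the wild-type mean, was lowest in wild-type replicate 2 (-0.81) and knock-in replicate 3 (-0.89), the libraries in which Xist was abundant. The neighbouring glutathione transferase genes had log2 fold changes of -0.78 for Gsta4, -2.1 for Gsta1, -2.28 for Gsta2 and -2.45 for Gm10639; Gsta1 and Gm10639 are outside the naming rule. None passed in the main fit, but Gsta4 passed in DESeq2 (adjusted p = 0.001167), in edgeR with no filter (adjusted p = 0.004869) and in the authors' table (adjusted p = 0.0009488). With no filter, edgeR also called Gsta1 and Gsta2 lower (adjusted p = 0.009488 for Gsta2). These paralogs can share reads, so the values of Gsta1, Gsta2 and Gm10639 are uncertain. Lower NRF2 activity stays open. Its 12 tested target genes had a median of -0.07, above the bound of -0.1 set in advance by less than their spread, and 10 of them were negative, with Gstm1 at -0.37.

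Lower pigment cell genes may reflect fewer pigment cells or lower expression in them, and counts of whole tissue do not separate these. Less lateral wall tissue was argued against by the strial marginal cell and fibrocyte lists, whose medians were -0.01 and 0.04. A uniform loss of all cells that express melanosome genes was argued against by the melanosome genes, of which 8 were tested, since they did not share 1 log2 fold change. Cochran's Q across these genes gave p = 5.92e-41, a chi-square approximation that rests on the fitted standard errors and takes genes as independent. With Dct and Pmel left out, the log2 fold changes of the other 6 ran from -2.69 to -0.23. The same chi-square approximation over these gave p = 1.53e-19. These 6 still held Slc24a5, at -0.23, and Pmel and Slc24a5 were not left out together. Dct, Slc45a2, Mlana, Tyr and Trpm1 ran from -2.69 to -1.89, and Tyrp1 was at -1.13. Whether those genes share 1 change was not tested. A loss of some cells that express melanosome genes, with Pmel and Slc24a5 expressed by others, stays open. So does an effect of the allele within cells.

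Higher values of cartilage and fat genes and of some gland genes may come from tissue dissected with the cochlea or from the genotype, and the design does not separate these. Salivary tissue was tested with 18 genes listed before their values were seen. The 6 that passed the filter had a median log2 fold change of 0.17, with 3 positive, under the bound of 0.5 set in advance. All 6 had counts in every wild-type library, so a small amount of gland tissue need not raise their median. Amy1 was the highest of the 6, at 1.59 (edgeR's quasi-likelihood test, unadjusted p = 0.004163, adjusted p = 0.9658). It was at 18.714, 29.587 and 75.634 CPM in knock-in and at most 16.454 CPM in wild-type. The list had left out Car6, Pip and Bpifa2, already seen as higher, so it excludes nothing. Of the 12 genes that the main fit did not test, 8 had more counts in knock-in and 4 fewer, in differing libraries: Cst10 had 4, 17 and 41 in knock-in and 1 in wild-type, Dcpp1 had 4, 8 and 140 in knock-in, Mucl2 had 1034, 0 and 0, and Muc19 had 189 in wild-type, 182 of them in replicate 3, and 21 in knock-in. Bpifb2 had 80 in wild-type, 78 of them in replicate 3, and 1 in knock-in. With no filter, edgeR called Amy1, Cst10, Dcpp1 and Mucl2 higher and none of the 18 lower, and DESeq2 called Cst10 higher. Younger knock-in mice cannot be told apart from other explanations, since growth genes that decline with age had a median of 0.07 and ages per mouse are not in the labels.

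With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2 genes higher and 5 lower, and the highest other split called 1 in a direction; in each case 1 split, the real one, reached the real count. The real split called 12 lists and the highest other 17, and 7 splits called at least 12. For the pigment cell list, limma's camera gave 5.49e-16 as its unadjusted value in the real split and 0.00259 as the smallest in another, and 1 split, the real one, reached the real value.

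Carried-over donor DNA around Hgf could change nearby genes. Of 33 tested genes within 5 Mb, 1 had an unadjusted p under 0.05 in edgeR's test, 3.0% (exact 95% interval 0.08% to 15.8%), which is too few genes to exclude the explanation.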
